A study of Homo sapiens with 4 samples.

How the data were processed

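RNA of MCF-7 cells infected with a miR-9 overexpression lentivirus or a control lentivirus was extracted with Trizol, made into libraries with a TruSeq RNA kit and sequenced on an Illumina NovaSeq, per the labels' protocols. The labels name 2 miR-9 and 2 vector libraries. The series text speaks of 2 repeats and the treatment protocol of triplicates, and 2 libraries per group were used here. Bowtie 0.12.2 and the genome builds hg38 and hg18 are named, without a role, in the submitters' processing notes. The read counter, the normalization tool, the strandedness and the test behind the gene selection are not given in the sources used here.

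The deposited values are a signal of normalised gene read counts, that is counts that the authors appear to have divided by one size factor per library, to judge from the values themselves. All values were whole multiples, within 0.01, of one step per library (0.954 and 1.01 in the miR-9 libraries, 0.96 and 1.06 in the vector libraries). Those steps correspond to 5338305, 5315624, 5314797 and 4794301 reads on the listed genes. The listed genes are part of each library, so these sums are not its depth, and too few of the values are low to test the steps further. No count model was therefore used to compare the groups. The steps served only for a chi-square comparison of pairs of libraries, over genes with at least 20 reads in the pair, which covers counting error alone. The design written before the data were examined had counts as its first choice and gave limma on log2 values for normalised values, and the latter was used. Each deposited table held the 2605 genes of the authors' list of differing genes, per the file headers with gene coordinates, biotype and transcription factor family. The start and end of all 2605 genes equalled those of GENCODE release 29 on GRCh38, so coordinates are given on that build. Columns of other samples that were left out numbered 0.

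Values were transformed to log2(value + 1), with a mean of at least 1 over the 4 libraries required, which removed no gene. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust settings, with statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment over the listed genes and a threshold of 0.05. Log2 fold changes are miR-9 minus vector on the log2(value + 1) scale, which understates the change of low genes. Means ± SD are of the deposited values. Genes at 0 in both libraries of a group are given without a fold. Because the authors chose the genes on the same libraries, p-values are too small to serve as a test of whether each gene differs. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, since the counting is not described.

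The analysis used 25 gene lists written from textbook knowledge before the data were examined, of which 18 had at least 5 listed members and were tested with camera (preset correlation 0.01) against the other listed genes, adjusted over the lists. List names were matched by gene identifier, including current and older symbols. The genes named in the text were also fixed by a rule at that time. They are the 12 genes with the largest rise and the 12 with the largest fall among genes past the test with a mean of at least 1 and non-overlapping groups, up to 4 members of each list with the smallest p, the host transcripts of miR-9, and ESR1, CDH1, VIM, LIFR, MTHFD2, FOXO1, ONECUT2 and REST. Genes named outside the rule are said to be so, and the same rule at a mean of at least 100 was added after the data were seen. Seed sites (8mer or 7mer-m8) of 8 microRNA families were searched in the longest annotated 3' UTR of protein-coding genes of GENCODE release 29. Bootstrap intervals used 2000 resamples of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

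The steps were tested on simulated data with the real genes' means and 2 against 2 libraries, with 200 of 2605 genes changed. All of the 2-fold changes (100%) and 99% of the 1.5-fold changes were recovered, with 9 false calls (4.33% of the calls), 0 of 17 unchanged lists were called, and a lowered level of genes with a site was recovered as -0.20 on the log2 scale. The simulated genes varied independently with a single dispersion, and most were unchanged, whereas the real genes were selected as differing. The simulation therefore tests neither the preset correlation of the list test nor the power of the seed-site test on such a selection. The single dispersion (9.4e-04) was a median over genes of estimates from 2 libraries, averaged over the groups. Such a median tends to lie below their mean, so the recovery and false-call rates may be too favourable for these libraries. The alternatives, listed before the data were examined unless named as added, were a pseudocount of 0.1, no filter, a mean of at least 5, quantile normalization, the replicate number as a block, a tested fold change above 1.5, leaving out each library, an estimated correlation and fry for lists, and other site definitions and a correction for 3' UTR length, GC content and expression for seed sites. Leaving out a library leaves 1 library in its group, which limma then assumes to vary like the other group. Added after the data were seen were the adjustment over all annotated genes, Fisher's exact tests of direction, and the correction of the lists for GC content, length and mean expression. In that adjustment the 58735 genes of the annotation were counted as tested, those outside the list with a p of 1.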

Results

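The series measured mRNA in cells labelled MCF-7, an established human breast cancer line that is commonly classed as luminal and estrogen receptor positive. Some levels in the vector libraries do not sit easily with that label. KRT17 was high, FOXC1 and TRIM29 lay above the median of the listed genes, FOXA1 lay below it and CDKN2A was present. Their values are given under the other observations. The identity of the cells was not tested, so the luminal and estrogen response lists below are read as lists of genes and not as a check of the cell type. The cells carried either a lentivirus that overexpresses microRNA-9 (miR-9) or a control lentivirus, here called vector, and stably infected cells were selected with puromycin. Each group had 2 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. The deposited tables held the same 2605 genes in every library, of which 2435 were protein-coding. These are the genes that the authors had already selected, from the same 4 libraries, as differing between miR-9 and vector. All other genes were not analysed here, and the full depth of the libraries is unknown. Over the listed genes the normalised read counts summed to 5093410 and 5374660 in the miR-9 libraries and to 5100970 and 5082000 in the vector libraries. The most abundant listed gene, MT-CO1, took between 4.06% and 4.67% of that sum. The 2 libraries of a group did not hold the same values. Their reads, taken from the steps of the values, gave a chi-square over its degrees of freedom of 7.88 in the miR-9 pair and 4.01 in the vector pair. That statistic covers counting error only, and reads copied by PCR are not independent molecules, so it argues only against one library deposited under both replicate numbers.

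The comparison asked which transcripts differed when miR-9 was overexpressed. Of the 2605 listed genes, 1439 were higher and 1134 were lower in the miR-9 libraries, and 32 did not pass limma's test at an adjusted p of 0.05. Most of the differences were small. The median rise was 1.26-fold and the median fall 1.37-fold. The falls reached further, with 395 genes lower and 221 genes higher by more than 1.5-fold, and 158 lower and 60 higher by more than 2-fold. In 2599 genes (99.8%) both miR-9 libraries lay on the same side of both vector libraries, where chance gives 33.3%. Because the genes were selected on these libraries, the counts and adjusted p-values describe the list and are not independent evidence. Without vector replicate 1, 1684 genes passed in place of 2573, and when a fold change above 1.5 was tested, 109 passed (23 higher, 86 lower).

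The host transcripts of miR-9 give no check of the labels, since 0 of the 7 host transcript names looked for were among the listed genes. Of the 8 single genes fixed in advance, MTHFD2 and LIFR were listed. ESR1, CDH1, VIM, FOXO1, ONECUT2 and REST were not analysed here. MTHFD2, a mitochondrial one-carbon enzyme (chromosome 2, 74198562 to 74217565, GRCh38), was lower at 2444 ± 136 against 3128 ± 79.6 normalised reads (mean ± SD, n = 2 per group), a log2 fold change of -0.36 (SE 0.07, limma adjusted p = 2.2e-04). LIFR, the receptor of leukemia inhibitory factor (chromosome 5, 38474963 to 38608354), was higher at 2578 ± 168 against 2192 ± 176, a log2 fold change of 0.23 (SE 0.08, adjusted p = 0.0073). Without vector replicate 2 the LIFR change was 0.15 (adjusted p = 0.214). Of 30 genes written down in advance as reported targets of miR-9-5p, 7 were listed, and 6 of these were higher and 1 was lower. UHRF1, a DNA methylation cofactor, rose by 0.46 on the log2 scale, followed by CXCR4 (0.27), TLN1 (0.24), LIFR, STMN1 (0.22) and CAPZA1 (0.19), and MTHFD2 fell. STMN1 and CAPZA1 were named after their values were seen. LIFR and STMN1 held no 8mer or 7mer-m8 site of miR-9-5p in the longest annotated 3' UTR, while the others did. The directions of these genes are therefore not a test of genes with a seed site. CXCR4 and TLN1 did not pass without vector replicate 1, with log2 fold changes of 0.27 and 0.19, nor did CXCR4 without vector replicate 2, at 0.27. As a list these genes did not stand apart from the other listed genes (camera adjusted p = 0.248). In the adjustment over all annotated genes 2 of the 7 passed. Fewer targets passed as higher without vector replicate 1 or without vector replicate 2, while the mean log2 fold change of the 7 stayed at 0.18.

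Genes of the integrated stress and unfolded protein responses were lower together. All 27 listed genes of the 30 on this list passed the test, 27 lower and 0 higher, with a median log2 fold change of -1.13, or 2.19-fold lower. HERPUD1, a component of endoplasmic reticulum associated degradation (chromosome 16, 56932048 to 56944863), stood at 2360 ± 170 normalised reads in the miR-9 libraries and 7144 ± 192 in the vector libraries (mean ± SD, n = 2), a log2 fold change of -1.60 (SE 0.08, limma adjusted p = 2.66e-14). SEL1L, an adaptor of the same degradation pathway, fell from 2823 ± 186 to 1011 ± 68.2, PSAT1, an enzyme of serine synthesis and target of the transcription factor ATF4, from 3730 ± 81.6 to 1396 ± 61.4, and DNAJC3, a co-chaperone of the endoplasmic reticulum, from 3061 ± 172 to 1224 ± 45.6. Named after their values were seen, the chaperone HSPA5 had a log2 fold change of -1.45 and ATF4 itself one of -0.43. Camera, which compares a list with the other listed genes, gave an adjusted p of 1.25e-10 with its preset correlation of 0.01. With a correlation estimated from the 4 libraries (0.53 for this list) the adjusted p was 0.653. That form of camera rests on 2 residual degrees of freedom and has little power for any list, so it cannot decide whether this list stands apart. In a test adjusted over all 58735 annotated genes, 26 of the 27 members passed.

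**Figure D1:**
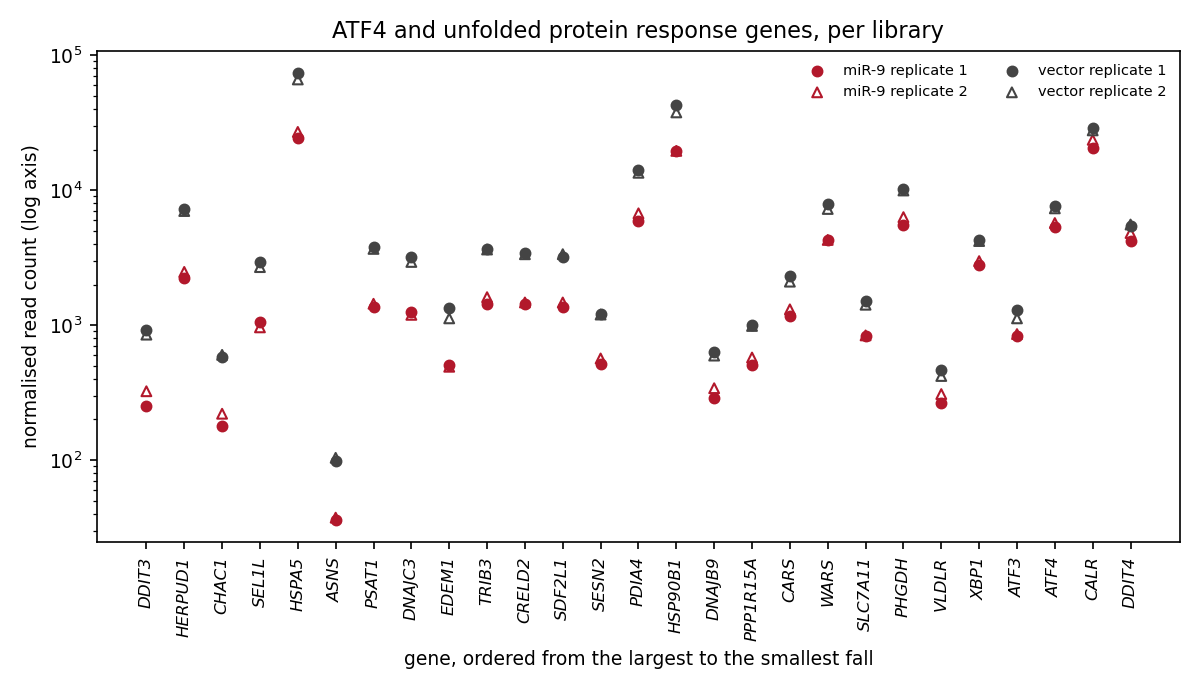
Normalised read counts (vertical log axis) of the 27 listed genes of the ATF4 and unfolded protein response list in each of the 4 libraries, ordered from the largest to the smallest fall. Circles are replicate 1 and triangles replicate 2, and both miR-9 libraries (red) lie below both vector libraries (grey) for every gene, as for HERPUD1 at 2360 against 7144 on average.

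Serine and one-carbon metabolism genes overlapped with that group. Of 9 listed members 7 were lower and 2 were higher, with a median log2 fold change of -0.73, and 4 of the 9 also stand in other lists. PSAT1 and PHGDH are in the stress response list, MTHFD2 is among the reported targets and TYMS is in the DNA replication list. The serine list was not tested without PSAT1 and PHGDH. The stress response list holds only 30 names, so the other lower members, MTHFD2 included, do not show a change apart from the stress response. PSAT1 led the falls, followed by ALDH1L2, a mitochondrial formyltetrahydrofolate dehydrogenase (480.4 ± 46.8 to 222 ± 16.1), SHMT2, the mitochondrial serine hydroxymethyltransferase (8511 ± 349 to 4501 ± 502), and PHGDH, the first enzyme of serine synthesis (10040 ± 127 to 5938 ± 535). The 2 higher members, named after their values were seen, were TYMS (0.43), the thymidylate synthase, and MTHFD1 (0.23). The camera adjusted p was 0.0464, and 0.653 with an estimated correlation, which leaves little power here. The adjusted p rose to 0.0958 without miR-9 replicate 1, 0.0555 without miR-9 replicate 2, 0.0561 without vector replicate 2, 0.0818 with the replicate number as a block and 0.0523 after correction for GC content, length and mean expression, and Fisher's exact test of direction gave 0.11. That correction left the median at -0.73 (SD over members 0.60 before and 0.62 after).

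Cell cycle genes were slightly higher in the miR-9 libraries. On the DNA replication list 16 of 18 listed members were higher, GINS1 was lower and MCM4 did not pass (both named after their values were seen), with a median log2 fold change of 0.33. The replicative helicase subunit MCM6 rose from 1292 ± 73.8 to 1860 ± 95.7 normalised reads, MCM5 from 2452 ± 131 to 3165 ± 171, the checkpoint adaptor CLSPN from 670 ± 12.1 to 939.7 ± 42, and UHRF1 from 2558 ± 117 to 3525 ± 115. On the mitosis list all 15 listed members of 32 were higher, within a narrow range of 0.20 to 0.35 on the log2 scale. The mitotic kinases AURKA and PLK1 rose by 0.35 and 0.31, the survivin gene BIRC5 by 0.31 and cyclin B1 (CCNB1) by 0.30. Camera gave adjusted p-values of 0.026 for DNA replication and 0.0355 for mitosis. With an estimated correlation (0.29 for DNA replication and 0.56 for mitosis), which leaves little power here, it gave 0.653 for both. Fisher's exact test of direction gave 0.00317 and 0.00224, but it treats the members of a list as independent. Correction for GC content, length and mean expression gave 0.0523 and 0.074, with the median moving from 0.33 to 0.27 for DNA replication (SD over members 0.21 and 0.23) and from 0.28 to 0.15 for mitosis (SD 0.04 and 0.08). In the adjustment over all annotated genes 11 of the 18 replication genes and 5 of the 15 mitosis genes passed. The mitosis list stood at 0.0567 without miR-9 replicate 2 and 0.0616 without vector replicate 2.

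Epithelial and mesenchymal markers did not move in opposite directions as lists. Among the luminal markers 6 of 7 listed members were higher. They included ELF3, an epithelial transcription factor (586 ± 66.1 to 1103 ± 176), the luminal pioneer factor FOXA1 (416 ± 35.6 to 687 ± 36.4), keratin 8 (KRT8, 22303 ± 1227 to 35041 ± 3770) and MUC1 (609 ± 66.3 to 906 ± 51.7). The tight junction gene CLDN7, named after its value was seen, was lower with a log2 fold change of -0.97. All 5 listed basal markers were higher, led by KRT17 (0.51), ITGA6 (0.47), FOXC1 (0.27) and TRIM29 (0.26). FOXC1 did not pass without vector replicate 1 (adjusted p = 0.0676), nor did TRIM29 without miR-9 replicate 2 (log2 fold change 0.16, adjusted p = 0.0656) or vector replicate 2 (0.24, adjusted p = 0.0548). Of 8 listed mesenchymal genes 5 were higher and 3 were lower. The calcium-binding protein S100A4 rose by 0.89, the microfibril gene FBN1 by 0.74 and the receptor kinase AXL by 0.37, while the collagen crosslinking enzyme LOX fell by 0.45. Adhesion and extracellular matrix receptor genes were higher in 12 of 15 cases, including ITGB5 (0.50) and LAMC1 (0.34), but the collagen receptor DDR2 fell 2.61-fold, from 2718 ± 220 to 1040 ± 46.1. None of these 4 lists passed camera, with adjusted p-values of 0.18 for luminal, 0.145 for basal, 0.465 for mesenchymal and 0.189 for adhesion genes.

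Members of the NF-kB, hypoxia, immediate early and estrogen response lists were lower more often than higher, and the interferon list was higher in most cases, but none of these lists passed camera. Of the NF-kB targets 7 of 9 were lower, among them CD83 (1006 ± 104 to 444 ± 26.5), the cytokines IL6 (507 ± 33.5 to 277 ± 6.52) and LIF (684 ± 18.1 to 444 ± 10.6), while SOD2, the mitochondrial superoxide dismutase, rose by 0.45 (list adjusted p = 0.0928). Of the hypoxia genes 9 of 12 were lower, including carbonic anhydrase CA9 (28.7 ± 0.12 to 4.49 ± 3.66), NDRG1 (-0.81) and VEGFA (-0.52) (list adjusted p = 0.135). Of the immediate early genes 8 of 10 were lower, including ATF3 (-0.50), JUN (-0.44) and MYC (-0.36), while BTG2 rose by 0.63 (list adjusted p = 0.135). Estrogen response genes were lower in 5 of 7 cases, with the secreted glycoprotein STC2 (1080 ± 30.9 to 467 ± 47.5) and cyclin D1 (CCND1, 3074 ± 12.7 to 1581 ± 65) among the lower ones (list adjusted p = 0.189). The 2 higher members, named after their values were seen, were MYB (1.02) and NRIP1 (0.34). The interferon list had 8 of 10 members higher, led by OAS1 (0.54) and DDX60 (0.49), and 2 that did not pass, ISG15 and IFI44L, named after their values were seen, with log2 fold changes of -0.16 and -0.60 (list adjusted p = 0.184). Of the p53 targets 4 were higher and 5 lower (list adjusted p = 0.559). These lists are not separate from the stress response list. XBP1 (estrogen response), ATF3 (immediate early) and SESN2 (p53), all lower, stand in that list too. MYC counts in both the estrogen response and immediate early lists, and BTG2 in both the p53 and immediate early lists.

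The nuclear oxidative phosphorylation, cholesterol and ribosomal protein lists did not pass camera. Nuclear oxidative phosphorylation genes were higher in 5 of 6 cases, such as NDUFA6 (0.36) and SDHA (0.32), with NDUFV1 lower (-0.28). Cholesterol genes were higher in 6 of 9 cases, such as ACAT2 (0.36) and LDLR (0.29), and lower for STARD4 (-0.53) and HMGCS1 (-0.50). Cytosolic ribosomal protein genes were lower in 7 of 8 cases, such as RPL22 (-0.35) and RPS25 (-0.34). Camera gave adjusted p-values of 0.296, 0.456 and 0.184 for these 3 lists. After correction for GC content, length and mean expression they were 0.458, 0.686 and 0.074, and the median of the ribosomal protein list moved from -0.21 to -0.42 (SD over members 0.20 and 0.24). A further 7 lists had fewer than 5 listed members and were not tested as lists. Of the leukocyte markers 0 were listed, and of the endothelial markers ENG was (-0.80, moving to -0.64 with an adjusted p of 0.106 without vector replicate 1 and to -0.35 with 0.185 after quantile normalization). ITGA6 and ABCG2 (0.62) of the stem cell list and the histone genes HIST1H2BK (0.52) and HIST1H1C (0.56) were higher. UNC13A (2.22-fold) and VGF (1.99-fold) of the neuronal genes repressed by REST were lower. Of the microRNA machinery AGO2 was lower (-0.30) and DROSHA higher (0.22), and DDX5 was lower (-0.18), but AGO2, DROSHA and DDX5 did not pass without vector replicate 1 (adjusted p = 0.0585, 0.118 and 0.273), nor did DROSHA without vector replicate 2 (0.0536) or DDX5 without miR-9 replicate 2 (log2 fold change -0.10, adjusted p = 0.119) or vector replicate 2 (-0.20, adjusted p = 0.167). Of the mitochondrially encoded genes MT-ATP8 was higher (0.56), and MT-ND1 (0.15) and MT-CO1 (-0.14) did not pass, although MT-ND1 passed without miR-9 replicate 1 (adjusted p = 0.0023) and MT-CO1 without miR-9 replicate 2 (0.032). Adjusted over the list alone, the number of members past the threshold was as given for every list except DNA replication, where 17 were higher. The list of genes was chosen on these libraries, so that count is not independent evidence.

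**Figure D2:**
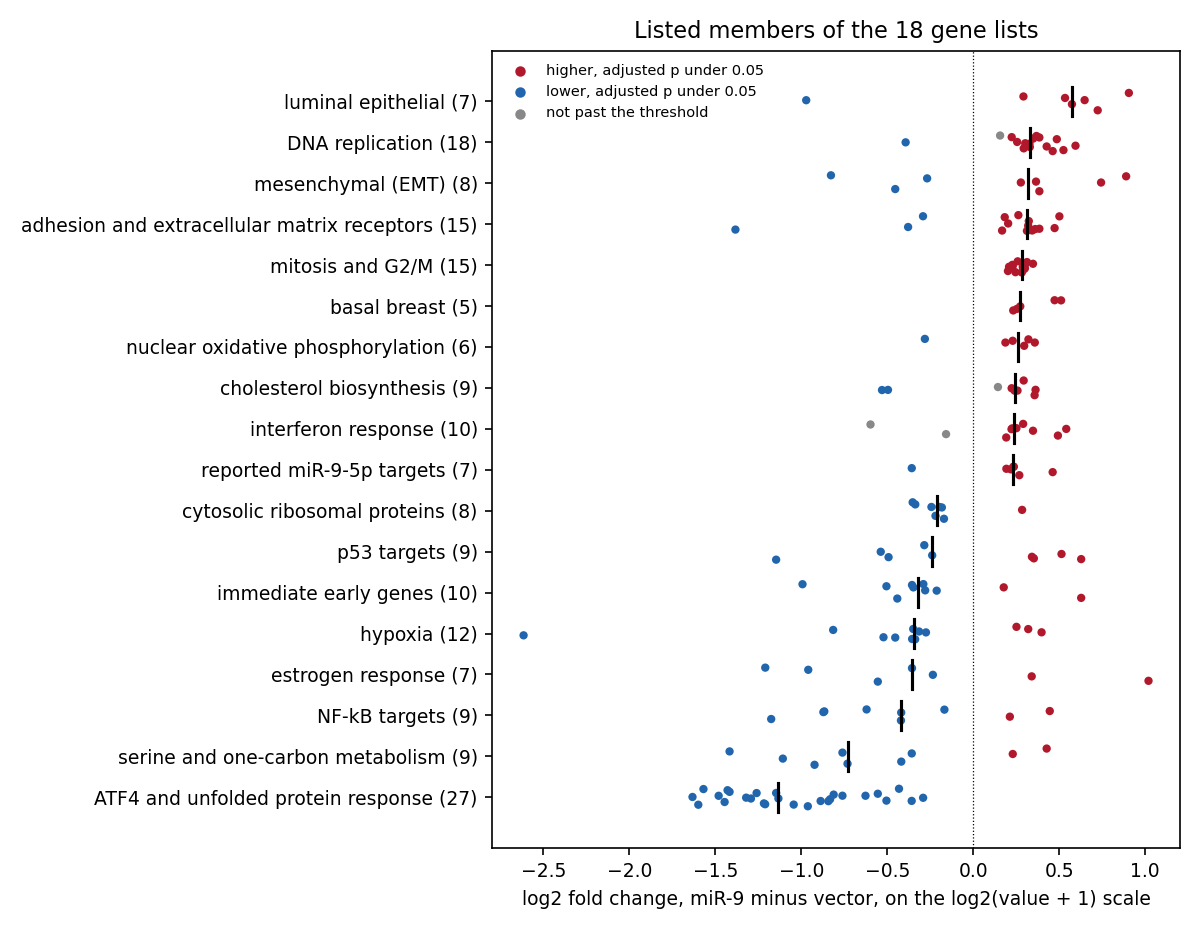
Log2 fold changes (horizontal axis, miR-9 minus vector) of the listed members of the 18 gene lists with at least 5 members, one point per gene, with the number of members in parentheses and black bars at the medians. All 27 members of the ATF4 and unfolded protein response list lie below 0 around a median of -1.13, and all 15 mitosis genes lie above 0 around 0.28.

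On the log2(value + 1) scale the gene with the largest rise was AL355075.4, annotated as an antisense transcript (chromosome 14, 20343048 to 20343685, GRCh38), at 758 ± 8.48 against 64.6 ± 3.11 normalised reads (n = 2), a log2 fold change of 3.53 (SE 0.15, limma adjusted p = 3.93e-15). It overlaps RPPH1, the RNA of ribonuclease P, over 333 of its 638 bases, and contains H1 promoter sequence, so its reads cannot be assigned with certainty. With a pseudocount of 0.1 it ranked 12th, behind 11 genes listed at 0 in both vector libraries, where the pseudocount sets the size of the rise. The other genes among the 12 largest rises had low values. HIST2H4B, a histone gene with near-identical copies and therefore uncertain, was at 37.4 ± 17.2 against 3.56 ± 0.96, and AL391056.1 at 16.2 ± 1.42 against 2.02 ± 0.14. The other 9 (ECEL1P3, SNORA80E, AC048344.4, EAF1-AS1, AC024575.1, AC005343.1, TREHP1, SPDYE16 and LHX9) were listed at 0 in both vector libraries and at 11.1 or less in each miR-9 library. The gene with the largest fall on that scale, EIF3CL, a near-identical copy of EIF3C and for that reason uncertain, was at 52.6 ± 1.46 against 798 ± 434, and did not pass without miR-9 replicate 1 or without miR-9 replicate 2 (adjusted p = 0.168 in both). INHBE, an inhibin beta subunit gene (chromosome 12, 57452323 to 57459280), fell 7.42-fold, from 372 ± 32.3 to 49.2 ± 3.4 (log2 fold change -2.89, SE 0.19, adjusted p = 3.55e-12). IZUMO1 (28.8 ± 12.2 to 2.95 ± 0.12), TMOD2 (18.5 ± 5.12 to 1.94 ± 1.31), MIOX (12.9 ± 4.79 to 0.98 ± 0.04), C1orf194 (10.8 ± 5.74 to 1.01 ± 1.43) and RFX3-AS1 (12.4 ± 7.99 to 1.43 ± 2.02) were also among the 12 largest falls. ZSCAN10, CYP21A1P, AL451042.1, AC119044.1 and LINC01234, of which CYP21A1P and AC119044.1 are pseudogenes, were listed at 0 in both miR-9 libraries. Of these 24 genes, 16 failed the test without at least 1 of the 4 libraries and TREHP1 and AC048344.4 then dropped below the minimum mean, while AL355075.4, HIST2H4B, AL391056.1, INHBE, IZUMO1 and TMOD2 passed without each.

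Genes with a miR-9-5p seed site in the 3' UTR were not distinguishable from the others by their mean change. Among 2429 listed genes with an annotated 3' UTR, 358 carried an 8mer or 7mer-m8 site and 2071 did not. Their median log2 fold changes were 0.20 and 0.23, and the mean difference (site minus no site) was -0.020, with a 95% bootstrap interval over genes of -0.087 to 0.043. Limma's camera gave an adjusted p of 0.927 over the 8 microRNA families tested (0.463 before adjustment). Genes with a site were lower in 167 of 358 cases (46.6%) and the others in 849 of 2071 (41.0%), a difference in direction with p = 0.0485 in a two-sided Fisher's exact test chosen after the data were seen. Of 4262 other 7mers found in a like number of 3' UTRs, 22.1% had a lower median. Genes are not independent replicates, and the listed genes exclude those the authors did not find to differ. The seed of the other arm, miR-9-3p, gave a camera value of 0.603 before and 0.927 after the same adjustment. With 8mer sites alone the difference was 0.035, and with 7mer-A1 sites added (585 genes with a site) it was -0.040, with 46.7% against 40.3% of genes lower (two-sided Fisher's exact p = 0.00705, and 0.0128 after correction for 3' UTR length, GC content and expression). With the same sites and without correction the test gave 0.0128 for miR-9-3p. Of the 6 families that were not introduced, it gave 0.00433 for miR-21-5p and 0.00275 for miR-200bc, with lower genes more frequent among those with a site, but 0.15 for let-7, 0.437 for miR-124-3p, 0.139 for miR-122-5p and 0.735 for miR-1, so the difference in direction is not particular to miR-9-5p.

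**Figure D3:**
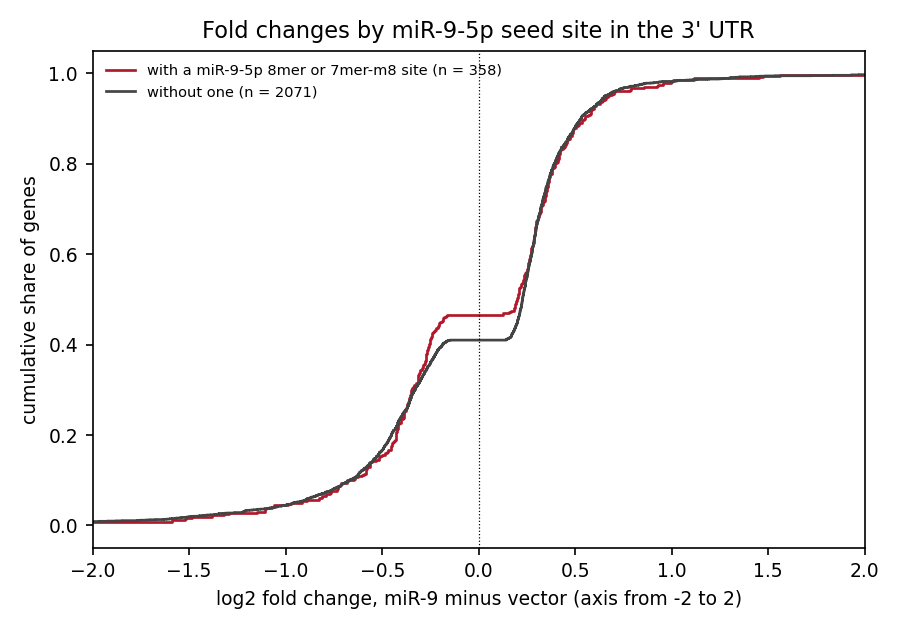
Cumulative share of genes (vertical axis) against log2 fold change (horizontal axis, miR-9 minus vector, drawn from -2 to 2) for the 358 listed genes with a miR-9-5p site in the 3' UTR (red) and the 2071 without (grey). The flat middle part reflects a list without genes of small change, and the curves part there, at 46.6% and 41.0%.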

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

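Alternatives chosen after seeing the data were the adjustment over all annotated genes, the tests of direction and the correction of the lists. The number of genes past the threshold (2573) stayed within 1.5 times under a pseudocount of 0.1 (2572), a mean of at least 5 (2555), quantile normalization (2321, of which 2309 were shared with the 2573) and no filter, which removed no gene. A tested fold above 1.5 left 109 genes, 23 higher and 86 lower, and 0 reported targets higher. Counting every annotated gene as tested left 1304, 663 higher and 641 lower. Leaving out each library gave 1684 to 2544 genes (1684 without vector replicate 1), 876 to 1429 higher and 808 to 1115 lower, 2 to 4 lists, 2 to 6 reported targets higher, and a seed-site difference of -0.033 to -0.0076. The seed-site difference reversed to 0.035 with 8mer sites alone (p = 0.945), was -0.040 with 7mer-A1 sites added (p = 0.31 by camera, 0.00705 by Fisher's exact test of direction) and, at -0.020, passed Fisher's exact test of direction (p = 0.0485); the cause was not tested. Of the lists, 4 passed with the preset correlation, 0 with an estimated one, 13 with fry and 3 with Fisher's exact test of direction (stress response, mitosis and DNA replication). After correction for GC content, length and mean 1 passed. The estimated correlation rests on 2 residual degrees of freedom and leaves little power for any list. Fisher's exact test of direction treats the members of a list as independent. The fry test compares a list with no change and not with the other listed genes. Its 13 passes carry little weight, because the members had been selected as differing. All 27 stress response genes lay below 0 under each setting of the gene test, and all 27 passed it except with a tested fold above 1.5 (19 passed), without vector replicate 1 (26), without vector replicate 2 (26) and in the adjustment over all annotated genes (26). Quantile normalization moved the median log2 fold change of all listed genes from 0.21 to 0.14, left each list's number of members above and below 0 unchanged, but fewer passed as higher on the mitosis (15 to 12), adhesion (12 to 9), interferon (8 to 7), luminal (6 to 5), reported target (6 to 5), cholesterol (6 to 5), oxidative phosphorylation (5 to 4), hypoxia (3 to 2), NF-kB (2 to 1) and immediate early (2 to 1) lists and as lower on the mesenchymal list (3 to 2), 1 more interferon gene passed as lower, and MT-ND1 stood at 0.22 (adjusted p = 0.00582). Among the single genes and lists it left 139 results with the same call. The replicate numbers do not pair the samples in the labels, and the replicate 1 deviations of the groups correlated at 0.0014 over genes. With the replicate block 2579 genes passed (1440 higher, 1139 lower), 2569 of them shared, the seed-site difference was -0.020, 6 reported targets were higher, and 3 lists passed, the serine list standing at 0.0818. DESeq2, other size factors, library totals and limma-voom were not run, because the values are normalised and the reads taken from their steps could not be tested further. Depth limits the genes of largest change, many of which rest on fewer than 12 normalised reads.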

Other observations

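The gene groups, the higher expression minimum, the neighbour counts and the marker levels in the first paragraphs, and the tests of AL355075.4, were chosen after the results were seen. A screen of 62 groups taken from the deposited annotation (chromosomes, transcription factor families and repeated description terms) compared their directions with those of the other listed genes by Fisher's exact test, adjusted over the 62 groups. The test treats genes as independent, although near neighbours shared a direction more often than permuted directions did, as given below. The groups were not corrected for GC content, length or mean expression. Their p-values are therefore too small to be taken at face value. Transfer RNA synthetases, which charge tRNAs with amino acids, were lower in 12 of 13 cases (adjusted p = 0.00407), with log2 fold changes from -0.84 (CARS) and -0.83 (WARS) to -0.23 (NARS), and QARS higher at 0.23. CARS and WARS also stand in the stress response list, and the other 11 had 10 lower (Fisher's exact p = 0.00176, unadjusted). That list holds only 30 names written from textbook knowledge, so this does not show a change apart from the stress response. Transcription factors of the bZIP family were lower in 13 of 14 cases (adjusted p = 0.00351). Of these, 4 are in the stress response list, and 9 of the other 10 were lower, including ATF6 (-0.33), BACH1 (-0.39), CREB5 (-1.06) and JUN, with ATF5 higher (0.50). C2H2 zinc finger factors were lower in 33 of 42 cases (adjusted p = 3.4e-04), such as ZNF419 (-0.86) and SP1 (-0.21), with SNAI3 (1.56) and ZNF488 (1.26) higher. Genes with the words ribosomal protein in their description were lower in 20 of 28 cases (adjusted p = 0.00864), but 4 of the 28 are S6 kinases. Of the other 24, 19 were lower, 4 higher and 1 not past the test, and 10 are pseudogenes. Chromosome 19 had 114 genes higher and 52 lower (adjusted p = 0.00407) and chromosome 16 had 44 higher and 61 lower (adjusted p = 0.027). Quantile normalization left the number of members above and below 0 in each of these groups unchanged, but in some of them fewer members passed. Of the C2H2 factors 27 then passed as lower, of chromosome 19 99 as higher and 45 as lower, of chromosome 16 43 as higher and 54 as lower, and QARS did not pass.

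With a mean of at least 100 required, the largest rises after AL355075.4 were in ALPP, the placental alkaline phosphatase (268 ± 28.8 to 1117 ± 180), PSCA, a surface glycoprotein (378 ± 19.4 to 1441 ± 101), the matrix protein gene MGP (58.4 ± 14.8 to 169 ± 20.8) and PTBP2, a neuronal splicing regulator (372 ± 30.4 to 1033 ± 88.9; means ± SD of normalised reads, n = 2). The falls included UNC5B, a netrin receptor (412 ± 6.82 to 73.8 ± 15.7), KLHDC7B (681 ± 54.8 to 120 ± 10.4) and the fucosyltransferase FUT1 (231 ± 15.1 to 59.1 ± 13.5). Several of the genes of largest change are neighbours on the chromosome. ECEL1P3 (232349754 to 232351309) and ALPP (232378534 to 232382889) on chromosome 2 were both higher, and IZUMO1 (48740852 to 48746909), FUT1 (48748011 to 48755390) and FGF21 (48755559 to 48758333) on chromosome 19 were lower. Over all listed genes, 365 of 607 adjacent pairs with a gap of at most 50 kb (60.1%) moved in the same direction, against 50.7% when directions were permuted 10000 times (one-sided p = 1e-04, the smallest the permutations can give), and 1053 of 1973 pairs with larger gaps did (53.4%, p = 0.01). Overlapping genes are among the near pairs, and the counting of overlaps is not described.

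In the vector libraries the luminal keratins KRT8 and KRT18 averaged 22303 and 14439 normalised reads, above 99.5% and 98.8% of the listed genes. The basal keratin KRT17 averaged 17546 normalised reads, above 99.0% of the listed genes. FOXC1 and TRIM29 averaged 1696 and 1521, above 69.8% and 66.5%, while the luminal factor FOXA1 averaged 416, below the median of 957 over the listed genes. Of the other basal markers MSN lay above 97.2% and ITGA6 above 50.3%. The other luminal markers MUC1, ELF3, AP1M2 and CLDN7 lay above 35.4%, 34.5%, 30.9% and 9.48%. CDKN2A, a gene known to be deleted in MCF-7, averaged 4905 ± 214 in the vector and 5944 ± 836 in the miR-9 libraries (mean ± SD, n = 2). The levels of KRT17, FOXC1, TRIM29, FOXA1 and CDKN2A put the label MCF-7 and its luminal type in question, while KRT8 and KRT18 do not. The values are not corrected for gene length, ESR1 and most other markers were not analysed here, and the identity of the cells was not tested. Of 9 listed mitochondrial transcripts 5 were lower, 2 were higher and 2 did not pass. The 16S ribosomal RNA MT-RNR2 was lower (95504 ± 4458 to 70101 ± 5953), while MT-TL1 was higher (172 ± 6.45 to 297 ± 26.1).

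The lower level of the 27 stress response genes is the pattern most open to follow-up. Linear trends of fold change on GC content, transcript length and mean expression explained 5.32% of the variance, and the corrected median of the members was -1.16 (SD 0.39 over members; -1.13 before correction), with 27 of 27 below 0, so those trends do not account for it. Direct repression through miR-9-5p sites in most members is also excluded for 8mer and 7mer-m8 sites in 3' UTRs, since 2 of 27 members carried one (7.41%; DNAJC3 and EDEM1), against 164 of 981 other lower genes (16.7%; Fisher's exact p = 0.292). An indirect effect of miR-9 may underlie the falls, but a difference in culture state between the groups, such as medium age or glucose and amino acid supply, could also do so and was not tested, because the labels give no culture record and each group has 2 libraries.

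The rise of AL355075.4 on the log2(value + 1) scale may come from the construct or from the RNA it overlaps rather than from a gene of its own. Its annotated transcript holds 3 of the H1 promoter stretches looked for, and 0 other listed genes hold one, and H1 is a promoter used in some lentiviral vectors. The stretches belong to the annotated gene itself, so finding them shows only that reads of such a construct could be counted there. RPPH1 (chromosome 14, 20343075 to 20343407) lies inside the gene, with 333 bases of overlap. These explanations cannot be told apart from each other or from a real rise, since the vector sequences and the reads were not used here and the control lentivirus could carry the same promoter.

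Genes with a miR-9-5p site did not lie clearly below the others, although a lowered level is the textbook action of a microRNA. Whether differences in 3' UTR length, GC content or expression hide a lower level stays open. For 8mer and 7mer-m8 sites the corrected mean difference was -0.027, with a 95% bootstrap interval over genes of -0.0886 to 0.034, which meets the bound of -0.1 set in advance against this explanation. That bound was not enough, because the interval treats genes as independent and the genes were selected on their change. In intervals added after the data were seen, with 7mer-A1 sites the corrected difference was -0.048 (-0.0969 to 3.94e-04), and without miR-9 replicate 1 it was -0.052 (-0.1002 to -0.0038), past the bound and wholly below 0. The other leave-outs met the bound and crossed 0. Those intervals were -0.0962 to 0.0041 without miR-9 replicate 2, -0.0919 to 0.0045 without vector replicate 1 and -0.0984 to 4.6e-04 without vector replicate 2. For 8mer and 7mer-m8 sites the corrected lower end stayed at -0.093 or above whichever library was left out. Sites of 2 comparator microRNAs leaned further down than those of miR-9-5p. For miR-21-5p 51.0% and for miR-200bc 49.9% of the genes with a site were lower, and 4.27% and 2.10% of like 7mers had a lower median, against 22.1% for miR-9-5p. The absence of unchanged genes from the tables limits this test, and how far the selection shaped the comparison stays open.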
